A study of Homo sapiens with 14 samples.

How the data were processed

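RNA sequencing counts from 22Rv1 cells, an established human prostate cancer line, were taken as deposited. The labels define 7 groups of 2 libraries, 14 libraries in all: a control hairpin (shCtrl), a hairpin against FOXA1 (shFOXA1), cells with a degradable FOXA1 fusion (dTAG) at 0 h, 1 h and 24 h of depletion, and cells labelled WT and R219S in the same fusion background. The dTAG system marks a tagged protein for degradation when a small molecule is added. The titles of the shCtrl libraries name the line as 22Rv2 while their other labels say 22Rv1, and they were treated as 22Rv1. The labels do not say whether the WT and R219S libraries received the degrader.

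The deposited tables held raw read counts per gene, as whole numbers with a different total in each library and no normalization. Per the labels, the submitters' processing notes name STAR, featureCounts, DESeq2 and the build hg19, without versions, annotation or strand setting. The knockdown table had 57904 features and each dTAG table had 57905, with Ensembl identifiers, and the R219S table had 20243 features named by symbol. Both dTAG tables held the 0 h libraries, with identical counts for all 57905 features. Among the names in the R219S table, 26 had been turned into dates by a spreadsheet, and these features held 0.172% to 0.186% of a library's counts. They stayed in the fits and are not named. No coordinates are given, because the build of the counts differed from that of the annotation at hand. Per-sample columns not used numbered 0.

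Total counts per library ran from 21.6 M to 38.5 M. Groups came from the labels, and each comparison was fitted on its own 4 libraries with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM normalization, estimateDisp, glmQLFit with robust estimation and the quasi-likelihood F test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. All adjusted p-values for genes are from edgeR unless another tool is named. The 4 main comparisons were shFOXA1 against shCtrl, dTAG 1 h against 0 h, dTAG 24 h against 0 h, and R219S against WT. A joint fit of the 6 dTAG libraries tested 24 h against 1 h, and an interaction fit over the knockdown and 24 h tables tested whether the 24 h change differed from the knockdown change. Standard errors of log2 fold changes are approximate and were computed as the absolute fold change over the square root of F. Levels are in counts-per-million (CPM) with TMM scaling within a comparison unless the library total is named as the divisor.

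The labels do not state that replicates were separate cultures, so the p-values measure only the spread between these libraries. With 2 libraries per group, the replicate numbers shared by groups were not taken as pairing. Within groups, the counts varied more than Poisson counting allows: chi-square per degree of freedom was 2.04 to 4.04 in 6 of the groups and 11.8 in shFOXA1, over genes with at least 20 counts in the pair. For genes with 0 counts in a group, a fold is given as a lower bound from a floor of 3 counts over the group. For genes with 1 to 3 counts, the ratio is given with an exact 95% interval. Intervals and floors cover counting error only.

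The gene lists, the rule for named genes, the comparisons, their tests and the alternative settings were fixed before the data were examined. The lists covered androgen receptor targets, luminal, basal, neuroendocrine, fibroblast, endothelial and leukocyte markers, forkhead and partner transcription factors, cohesin with its loader and regulators, DNA replication and G1/S, mitosis and G2/M, replication-dependent histones, MYC targets and ribosome biogenesis, p53 targets, immediate early genes, NF-kB, interferon, TGF-beta, epithelial-mesenchymal transition, hypoxia and glycolysis, cholesterol and fatty acid synthesis, the unfolded protein and ATF4 response, heat shock proteins, and mitochondrially encoded mRNAs. Older names were matched through GENCODE 29 and RefSeq synonyms. CD24, PECAM1 and UHRF1 matched no feature in any table, and ACACA, BOP1, HIST1H2AB, HIST1H3B and HIST1H4E matched none outside the R219S table. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. Camera was repeated with an estimated correlation, and none of the list calls of the 6 comparisons passed then. In that form camera takes its degrees of freedom from the few libraries of a fit. The loss of calls therefore does not by itself measure correlation between members. At 24 h the mitosis list had an estimated correlation of -0.00685, below the preset 0.01, yet its unadjusted camera p went from 3.06e-13 to 0.0147. Other called lists had estimates far above the preset. In shFOXA1 they ran from 0.164 for cohesin to 0.781 for mitosis, except interferon genes (-0.00297). At 1 h the estimate was 0.626 for mitochondrially encoded mRNAs and at most 0.0758 for the other called lists. For lists with high estimates, the p-values at the preset overstate the evidence if the estimates hold. Members of a list that rose or fell were counted from the gene-wise edgeR test.

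By the rule, the named genes were FOXA1, then in each main comparison the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM, a symbol that is no placeholder and groups that did not overlap. Up to 4 members with the smallest p were added from each called list and from the androgen receptor, luminal, neuroendocrine and cohesin lists. For the interaction, the rule took the 4 genes with the smallest p among those called in opposite directions. The tests for 24 h against 1 h named no further genes. Some genes that the rule names are not reported here.

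The alternative settings chosen then were DESeq2 1.42.0 size factors, library size alone, other low-count filters, DESeq2 and limma-voom as tests, no robust estimation, a 2-fold minimum, the replicate number as a block, a joint fit of the depletion times and leaving out each library. A correction for GC content and transcript length was added after the data were seen. It used a loess trend (span 0.3, degree 2) of each library against the properties of the longest transcript in GENCODE 29. Overlaps of called genes were compared with the number expected from independence. In 20 simulated data sets all dTAG groups were drawn from the 0 h means, which gave the correlation that the shared 0 h libraries alone produce. No gene changed in these data sets, so their overlap of calls was bound to be small. The 0 h libraries were also split, 1 to each dTAG comparison, an alternative chosen after the data were seen.

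The steps were tested on simulated data made from the libraries, with 200 genes changed by 1.5-fold, 2-fold or 4-fold. edgeR recovered 71.6% to 86.6% of the 1.5-fold changes, 80.6% to 97.0% of the 2-fold changes and 95.5% to 100% of the 4-fold changes across the 6 comparisons. False calls were 3.57% to 8.84% of the calls. Camera called the raised set of 20 genes and 0 of the 20 random sets in each comparison. The simulated genes were drawn independently of each other. This test therefore could not show how camera does with correlated members. The GC correction lowered the calls made from a simulated trend alone in the 1 h comparison from 5876 to 11. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.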

Results

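Expression was measured by RNA sequencing in 14 libraries of 22Rv1 human prostate cancer cells. FOXA1 is a pioneer transcription factor of the luminal prostate lineage. It was lowered by a hairpin, targeted for induced degradation for 1 h or 24 h, or carried the R219S substitution. Each of the 7 groups had 2 libraries. Library totals were 34.3 and 36.5 M counts in shCtrl, 34.9 and 34.1 M in shFOXA1, 34.3 and 35.5 M at 0 h, 34.2 and 34.0 M at 1 h, 32.1 and 32.2 M at 24 h, 38.5 and 26.4 M in WT, and 21.6 and 25.8 M in R219S. Log2 fold changes are given with their standard error and levels with their standard deviation, each for 2 libraries per group. Levels in different tables come from separately counted tables and were not tested against each other.

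FOXA1 mRNA was lower in shFOXA1, at 298.5 and 304.8 CPM, than in shCtrl, at 402.3 and 434.5 CPM, a log2 fold change of -0.47 ± 0.062 (adjusted p = 0.000275). It was 0.721 times the control level, so most of the transcript remained. The degradation system acts on the protein, and FOXA1 mRNA does not measure its loss. The mRNA showed a log2 fold change of -0.0057 ± 0.033 at 1 h (adjusted p = 0.941) and rose by 0.23 ± 0.039 at 24 h (adjusted p = 7.6e-06). In R219S it was 703.3 and 681.2 CPM against 1019 and 1032 CPM in WT, a fall of log2 -0.57 ± 0.036 (adjusted p = 1.28e-45). Whether these counts came from the native gene, the tagged copy or an added copy was not resolved by the tables.

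**Figure D1:**
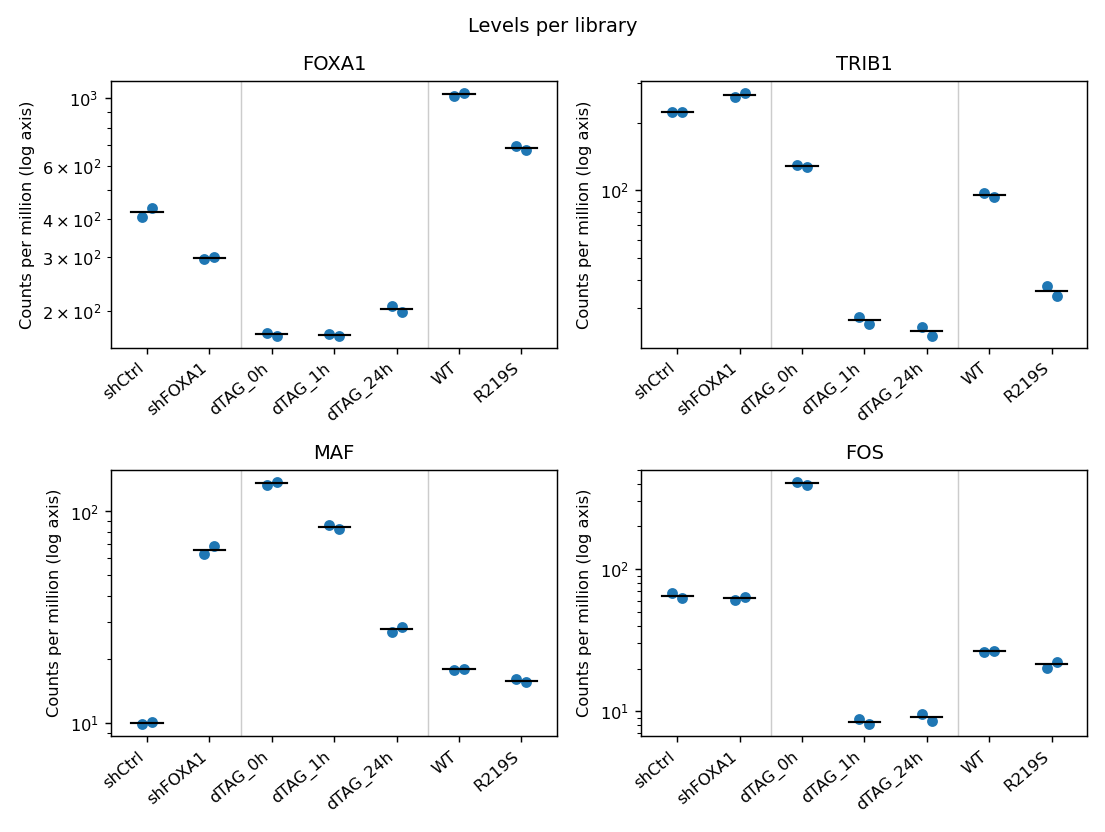
CPM (of the library total, log axis) of FOXA1, TRIB1, MAF and FOS in each of the 14 libraries; points are libraries, bars are means of 2 libraries, and vertical lines part the separately counted tables. FOS was near 402 CPM at 0 h and near 8.44 CPM at 1 h, and MAF was higher in shFOXA1 than in shCtrl while it was lower at 1 h and 24 h than at 0 h.

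The knockdown comparison asked which transcripts changed when FOXA1 mRNA was reduced. MAF, a bZIP transcription factor, rose from 9.93 ± 0.193 CPM in shCtrl to 66.7 ± 4.49 CPM in shFOXA1 (n = 2 each), a log2 fold change of 2.75 ± 0.089 (adjusted p = 7.32e-09). FKBP5, an androgen-responsive co-chaperone of steroid receptors, rose from 306 ± 6.66 to 841 ± 142 CPM. The luminal keratins KRT19 and KRT8 rose by log2 1.64 ± 0.077 and 0.78 ± 0.086. DKK1, a secreted inhibitor of Wnt signalling, fell from 8.47 ± 0.175 to 1.03 ± 0.453 CPM, a log2 fold change of -3.03 ± 0.24 (adjusted p = 1.33e-05).

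Of 19128 genes tested, 4506 were called, 2156 higher and 2350 lower, and 580 of them changed at least 2-fold (316 higher, 264 lower). The 10 largest rises after the rule were CYP4F22 (log2 4.06 ± 0.41), DGKG (3.76 ± 0.44), SLC26A3 (3.67 ± 0.22), SOCS2 (3.52 ± 0.47), ST8SIA6 (3.10 ± 0.30), KRT15 (3.04 ± 0.42), MAF, INMT (2.70 ± 0.19), NCMAP (2.45 ± 0.26) and HLX-AS1 (2.41 ± 0.42). Their adjusted p-values ran from 7.32e-09 to 0.0113. The 10 largest falls were LRRC26 (-4.03 ± 0.37), DKK1, RAB5IF (-3.01 ± 0.18), SMIM28 (-2.74 ± 0.31), C4orf48 (-2.67 ± 0.47), PCDH19 (-2.66 ± 0.27), CYBA (-2.61 ± 0.28), BHLHA15 (-2.51 ± 0.36), CALCA (-2.36 ± 0.39) and FGL1 (-2.35 ± 0.20), with adjusted p from 4.68e-06 to 0.011. The shFOXA1 libraries differed from each other more than any other pair, and the call count was 2421 without shCtrl replicate 1, 1713 without shCtrl replicate 2 and 6793 without shFOXA1 replicate 1. SOCS2 lost its call without shCtrl replicate 1 (adjusted p = 0.132) or 2 (adjusted p = 0.16), as did KRT15 (adjusted p = 0.242 and 0.286).

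All 26 mitosis and G2/M genes tested fell in shFOXA1 (median log2 -0.44; 26 adjusted over the list alone), as did 23 of 25 DNA replication and G1/S genes (median -0.46; 24 adjusted over the list alone). ANLN, which acts in cytokinesis, fell by 0.65 ± 0.063 on the log2 scale, CENPE, a kinetochore motor, by 0.67 ± 0.080, BUB1B by 0.53 ± 0.065 and TTK by 0.53 ± 0.072. The replication licensing gene CDC6 changed by -0.67 ± 0.075, MCM2 by -0.51 ± 0.059, MCM10 by -0.63 ± 0.077 and GINS2 by -0.61 ± 0.076. By camera the adjusted p was 6.01e-10 for each list, and the adjusted p was 0.496 with an estimated correlation. Among cohesin genes, 10 of 17 fell and 0 rose (12 and 1 adjusted over the list alone; median -0.27), among them ESCO2 (-0.56 ± 0.074), STAG1 (-0.46 ± 0.062), SMC3 (-0.38 ± 0.059) and CDCA5 (-0.56 ± 0.083). The cohesin list had camera adjusted p = 0.00289, and adjusted p = 0.496 with an estimated correlation. Of the 24 p53 targets, 9 rose and 1 fell (12 and 1 adjusted over the list alone; median 0.17), with the cell cycle inhibitor CDKN1A at 0.73 ± 0.063, BTG2 at 0.71 ± 0.068, SPATA18 at 0.47 ± 0.086 and ZMAT3 at 0.30 ± 0.062. The camera adjusted p was 0.00233 for p53 targets, 0.0706 without shCtrl replicate 1, and the adjusted p was 0.499 with an estimated correlation. ZMAT3 lost its call without shCtrl replicate 1 (adjusted p = 0.0692) or 2 (adjusted p = 0.0676).

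In the cholesterol and fatty acid list, 19 of 25 genes fell and 0 rose (22 and 1 adjusted over the list alone; median -0.47). HMGCS1, which starts the mevalonate pathway, changed by -0.99 ± 0.073, IDI1 by -0.85 ± 0.077 and DHCR7 by -0.79 ± 0.074. In the unfolded protein and ATF4 list, 21 of 24 fell and 1 rose (22 and 1 adjusted over the list alone; median -0.52), with XBP1, a transcription factor of the response, at -1.02 ± 0.070, SDF2L1 at -0.74 ± 0.064, MTHFD2 at -0.64 ± 0.061 and TRIB3 at -0.81 ± 0.080. Both lists had camera adjusted p = 4.37e-09, and adjusted p = 0.496 with an estimated correlation. Of 18 heat shock genes, 9 fell and 0 rose (10 and 1 adjusted over the list alone; median -0.19), including HSPH1 (-0.40 ± 0.061), HSPB1 (-0.34 ± 0.058), HSPE1 (-0.34 ± 0.071) and BAG3 (-0.36 ± 0.084). Camera gave adjusted p = 0.00289 for heat shock proteins, and adjusted p = 0.499 with an estimated correlation. HSPE1 and BAG3 lost their calls without shCtrl replicate 2 (adjusted p = 0.0767 and 0.195).

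Of 19 interferon-stimulated genes, 8 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.39). IFI6 fell from 13.1 ± 0.356 to 3.09 ± 0.159 CPM, HERC5 changed by log2 -0.97 ± 0.19, OAS3 by -0.52 ± 0.14, and MX1 rose by 0.64 ± 0.20. The list had camera adjusted p = 0.0147, adjusted p = 0.0737 when a minimum of 1 CPM was required, and adjusted p = 0.496 with an estimated correlation. OAS3 lost its call without shCtrl replicate 1 (adjusted p = 0.0772) or 2 (adjusted p = 0.133), and MX1 without shCtrl replicate 2 (adjusted p = 0.344) or with DESeq2 (adjusted p = 0.0556). Of 13 mitochondrially encoded mRNAs, 8 rose and 0 fell (10 and 0 adjusted over the list alone; median 0.22), with MT-CO1 at 0.30 ± 0.062, MT-CO2 at 0.28 ± 0.060, MT-ND5 at 0.26 ± 0.060 and MT-ND4L at 0.28 ± 0.066. By camera the adjusted p was 0.00395 for them, and the adjusted p was 0.496 with an estimated correlation. Without shCtrl replicate 2 the adjusted p was 0.122 for MT-CO1, 0.16 for MT-CO2, 0.179 for MT-ND5 and 0.284 for MT-ND4L. Without shCtrl replicate 1 it was 0.0528 for MT-CO1, 0.0521 for MT-CO2 and 0.0843 for MT-ND5.

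Of 28 androgen receptor targets, 10 rose and 4 fell in shFOXA1 (11 and 5 adjusted over the list alone; median 0.15), and the list did not pass (camera adjusted p = 0.0663; 0.0398 without shFOXA1 replicate 2). Besides MAF and FKBP5, the prostate kallikrein KLK4 rose by log2 0.70 ± 0.069 and PMEPA1 by 0.60 ± 0.057. Luminal identity genes went both ways, 4 up and 6 down of 22 (4 and 7 adjusted over the list alone; median -0.15; camera adjusted p = 0.387), with GRHL1 at -0.80 ± 0.11 and EPCAM at -0.52 ± 0.081 beside the higher KRT19 and KRT8. Of 20 neuroendocrine markers, 5 fell and 1 rose (8 and 2 adjusted over the list alone; median -0.32). UCHL1 changed by -2.03 ± 0.48, the granule protein CHGA by -0.62 ± 0.14, PEG10 by -0.24 ± 0.057, and CELF3 rose by 0.67 ± 0.067. The camera adjusted p was 0.0131 for neuroendocrine markers, and the adjusted p was 0.499 with an estimated correlation. PEG10 lost its call without shCtrl replicate 1 (adjusted p = 0.133) or 2 (adjusted p = 0.137), and UCHL1 without shCtrl replicate 1 (adjusted p = 0.097).

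The other lists did not pass in shFOXA1. The median log2 fold change was 0.26 for epithelial-mesenchymal transition (7 of 19 rose, 0 fell; adjusted p = 0.0561), 0.30 for fibroblast markers (1 of 9 rose; adjusted p = 0.0979) and 0.30 for NF-kB genes (5 rose and 3 fell of 13; adjusted p = 0.2). The first list passed without shCtrl replicate 2 (adjusted p = 0.0295) or shFOXA1 replicate 1 (adjusted p = 0.0461), and the second without shCtrl replicate 1 (adjusted p = 0.0205). Basal markers had 3 up and 4 down of 12 (adjusted p = 0.699), hypoxia and glycolysis 6 up and 1 down of 23 (0.255), immediate early genes 4 up and 6 down of 26 (0.222), MYC targets 2 up and 3 down of 23 (0.699), and histones 1 down of 11 (0.361). Forkhead and partner factors had 7 up and 8 down of 23, with a median of 0.043 and a mean of -0.055 (adjusted p = 0.699). TGF-beta genes had 6 up and 6 down of 23, with a median of -0.0071 and a mean of 0.048 (adjusted p = 0.699).

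The 1 h comparison asked which transcripts changed soon after degradation of the FOXA1 fusion began. The largest falls were among immediate early genes, which respond within minutes to growth factors. FOS went from 403 ± 15.3 CPM at 0 h to 8.44 ± 0.489 CPM at 1 h (n = 2 each), a log2 fold change of -5.58 ± 0.048. FOSB changed by -6.80 ± 0.055, EGR3 by -6.68 ± 0.070 and EGR1 by -4.23 ± 0.041. SGK1, a serum- and glucocorticoid-regulated kinase, rose from 13.2 ± 0.466 to 45.5 ± 0.0634 CPM, and the transcription factor CEBPB rose by log2 1.71 ± 0.087.

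Of 19397 genes tested, 3850 were called at 1 h, 2081 higher and 1769 lower, and 211 changed at least 2-fold (83 higher, 128 lower). The other large falls were EGR4 (-6.56 ± 0.37), EGR2 (-4.85 ± 0.22), FOXJ1 (-4.63 ± 0.39), NPAS4 (-3.83 ± 0.32), ATOH1 (-3.05 ± 0.22) and RNF138P1 (-2.39 ± 0.38), and the 10 largest falls had adjusted p from 4.39e-89 to 4.17e-07. The other large rises were LRRC26 (1.89 ± 0.44), C19orf81 (1.85 ± 0.26), ISLR2 (1.77 ± 0.34), DLX3 (1.59 ± 0.11), ASCL2 (1.55 ± 0.34), IER5L (1.43 ± 0.062), EDN2 (1.43 ± 0.076) and DDIT4 (1.37 ± 0.082). The call count was 2428 without dTAG_1h replicate 1, 2232 without dTAG_1h replicate 2 and 2058 with DESeq2. The 1 h libraries differed for LRRC26 (52 and 134 counts) and C19orf81 (81 and 138 counts). Without dTAG_1h replicate 2 the log2 fold change was 1.06 for LRRC26 and 0.96 for ASCL2, and both lost their calls. The changes at 1 h rose with the GC content of the transcript (Spearman's rho = 0.406 across 15114 genes, which are not independent replicates). They fell with its length (rho = -0.272). After a correction for GC content and length, chosen after the data were seen, 2607 genes were called, 1992 of them among the 3850.

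Of 26 immediate early genes, 20 fell and 2 rose at 1 h (22 and 2 adjusted over the list alone; median log2 -0.77). Camera gave adjusted p = 1.46e-16, and adjusted p = 0.428 with an estimated correlation. The 0 h libraries held more of these transcripts than the control libraries of the other tables: the median log2 ratio of 0 h was 1.23 over shCtrl and 0.92 over WT. All 13 mitochondrially encoded mRNAs fell (13 adjusted over the list alone; median -0.23), with MT-ND2 at -0.30 ± 0.023, MT-ND4L at -0.29 ± 0.024, MT-ATP6 at -0.25 ± 0.022 and MT-ND1 at -0.24 ± 0.024. They had camera adjusted p = 2.05e-06, and adjusted p = 0.663 with an estimated correlation. In the cholesterol and fatty acid list 16 of 25 rose and 1 fell (17 and 1 adjusted over the list alone; median 0.12), with the lipogenic regulator SREBF1 at 0.80 ± 0.045, MSMO1 at 0.41 ± 0.036, FDPS at 0.32 ± 0.034 and SCD at 0.27 ± 0.035. By camera the adjusted p was 4.63e-05 for that list, and the adjusted p was 0.428 with an estimated correlation.

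Of 23 MYC target and ribosome biogenesis genes, 8 fell and 1 rose at 1 h (13 and 1 adjusted over the list alone; median -0.095), among them DDX21 (-0.25 ± 0.030), GNL3 (-0.24 ± 0.031), NOLC1 (-0.14 ± 0.029) and NIP7 (-0.25 ± 0.057). The list had camera adjusted p = 0.0028, adjusted p = 0.0663 without dTAG_1h replicate 2, and adjusted p = 0.469 with an estimated correlation; NOLC1 lost its call without dTAG_1h replicate 1 (adjusted p = 0.0552). Of 18 heat shock genes, 7 fell and 2 rose (8 and 2 adjusted over the list alone; median -0.076), with DNAJB1 at -0.34 ± 0.039, DNAJA1 at -0.26 ± 0.030, HSP90AA1 at -0.14 ± 0.025 and CHORDC1 at -0.29 ± 0.052. The camera adjusted p was 0.0459 for heat shock proteins, and the adjusted p was 0.663 with an estimated correlation. That call ended without dTAG_0h replicate 1 (adjusted p = 0.071), dTAG_0h replicate 2 (0.204), dTAG_1h replicate 1 (0.21) or dTAG_1h replicate 2 (0.0683), and with the replicate number as a block (0.0794).

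Androgen receptor targets went both ways at 1 h, 5 up and 7 down of 29 (6 and 7 adjusted over the list alone; median 0.0069, mean -0.093, camera adjusted p = 0.548). MAF changed by -0.69 ± 0.038, C1orf116 by -0.24 ± 0.037 and the elongation factor gene ELL2 by -0.15 ± 0.029. Of 22 luminal genes, 9 rose and 2 fell (10 and 2 adjusted over the list alone; median 0.097, adjusted p = 0.0564), with the tight junction gene CLDN4 at 0.83 ± 0.033, KRT19 at 0.20 ± 0.025 and KRT8 at 0.19 ± 0.024. Of 17 neuroendocrine markers, 5 rose and 2 fell (5 and 2 adjusted over the list alone; median 0.016, mean -0.014, adjusted p = 0.671), with VGF at 0.31 ± 0.030, CELF3 at 0.34 ± 0.046, ONECUT2 at -0.50 ± 0.046 and SRRM4 at -0.19 ± 0.034. Of 17 cohesin genes, 4 fell and 1 rose (6 and 2 adjusted over the list alone; median -0.058, adjusted p = 0.395), with the loader NIPBL at -0.27 ± 0.039, STAG1 at -0.28 ± 0.052, PDS5A at -0.15 ± 0.032 and the separase gene ESPL1 at 0.18 ± 0.046. PDS5A lost its call without dTAG_1h replicate 2 (adjusted p = 0.0604).

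The remaining lists did not pass at 1 h. Replication and G1/S genes had 4 up and 1 down of 25 (median 0.042, adjusted p = 0.522) and mitosis genes 2 up and 3 down of 26 (median -0.0084, adjusted p = 0.828). The unfolded protein and ATF4 list had 11 up and 5 down of 24, with a median of -0.022 and a mean of 0.099 (adjusted p = 0.395), p53 targets 8 up and 3 down of 24 (0.862), TGF-beta genes 7 up and 2 down of 22 (0.395), and epithelial-mesenchymal genes 2 up and 5 down of 17 (0.395). Basal markers had 2 up and 2 down of 12 (0.211), forkhead and partner factors 5 up and 4 down of 21 (median -0.021, mean 0.15; 0.79), hypoxia genes 1 up and 4 down of 23 (0.592), interferon genes 1 up and 1 down of 20 (0.828), and NF-kB genes 1 up and 1 down of 14 (0.548). Histones had 1 down of 12 (0.395), leukocyte markers 1 down of 7 (0.395) and fibroblast markers a median of -0.097 over 8 genes (0.777).

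The 24 h comparison asked which transcripts changed after a day of depletion. The sample titles name no vehicle group held for 24 h and no untagged cells given the degrader. Time in culture and the small molecule itself were therefore not separated from loss of FOXA1. SPDEF, an ETS factor of luminal secretory cells, fell from 41.3 ± 2.11 CPM at 0 h to 2.07 ± 0.337 CPM at 24 h (n = 2 each), a log2 fold change of -4.32 ± 0.11 (adjusted p = 1.8e-24). FOLH1, which encodes prostate-specific membrane antigen, fell from 324 ± 5.32 to 122 ± 5.54 CPM. The DNA replication genes RRM2, MCM2, PCNA and CDC6 fell by 2.40 ± 0.046, 2.01 ± 0.049, 1.63 ± 0.046 and 2.50 ± 0.073 on the log2 scale. The transcription factor SOX9 rose by 1.73 ± 0.046, and CD44 and KRT15, which mark basal cells, rose by 1.55 ± 0.045 and 1.63 ± 0.073.

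Of 19607 genes tested, 9195 were called at 24 h, 4333 higher and 4862 lower (47.1% higher; 54.2% higher, 5025 against 4248, when scaled by library size only), and 1544 changed at least 2-fold (680 higher, 864 lower). Among the largest rises were HS3ST3B1 (3.19 ± 0.38), ISLR2 (3.15 ± 0.26), TSPAN18 (3.14 ± 0.15), CCN5 (3.03 ± 0.34), FIGNL2-DT (3.01 ± 0.29), ENC1 (2.85 ± 0.045), CITED4 (2.83 ± 0.31), the cell adhesion gene NRCAM (2.78 ± 0.051) and SPINK2 (2.61 ± 0.11), with adjusted p from 6.41e-30 to 2.85e-08. ATOH1, a neurogenic bHLH factor, had 424 counts at 0 h and 0 at 24 h, at least 134-fold lower. TRGC1, whose locus also gives the TARP transcript of prostate cells, fell from 53.5 ± 0.239 to 0.154 ± 0.0876 CPM (log2 -8.41 ± 0.16). UGT2B15, which glucuronidates androgens, had 822 counts at 0 h and 3 at 24 h, a ratio of 260 (95% interval 88.7 to 1260). The same ratio was 240 (42.7 to 9520) for APOA5, 145 (25.7 to 5770) for UGT2B10, 122 (33.5 to 1020) for DSCAM-AS1 and 78.8 (21.5 to 656) for TRGC2. FOSB (-6.91 ± 0.062), EGR3 (-6.82 ± 0.081) and FOS (-5.52 ± 0.057) completed the 10 largest falls. Reads of the UGT2B family, of TRGC1 and TRGC2 and of antisense genes such as DSCAM-AS1 and HLX-AS1 can be shared with a close relative or the opposite strand, and the strand setting is not stated.

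All 25 DNA replication and G1/S genes fell at 24 h (25 adjusted over the list alone; median log2 -1.61), as did all 26 mitosis and G2/M genes (26 adjusted over the list alone; median -0.76), among them CDK1 (-1.45 ± 0.046), ANLN (-1.08 ± 0.053), BUB1B (-1.12 ± 0.060) and the proliferation marker MKI67 (-0.82 ± 0.044). Camera gave adjusted p = 6.17e-15 and 3.52e-12, and adjusted p = 0.164 for each with an estimated correlation. Of 23 MYC target and ribosome biogenesis genes, 22 fell (22 adjusted over the list alone; median -0.48), with TCOF1 at -1.15 ± 0.050, NOLC1 at -0.86 ± 0.037, NOP56 at -0.73 ± 0.037 and nucleolin (NCL) at -0.62 ± 0.035. They had camera adjusted p = 2.07e-08, and adjusted p = 0.266 with an estimated correlation. Of 26 immediate early genes, 22 fell and 2 rose (22 and 2 adjusted over the list alone; median -0.91; camera adjusted p = 1.38e-08, and adjusted p = 0.164 with an estimated correlation), with EGR1 at -4.11 ± 0.048.

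Of 18 heat shock genes, 15 fell and 0 rose at 24 h (15 and 0 adjusted over the list alone; median -0.48), with HSPD1 at -0.88 ± 0.034, HSPA8 at -0.58 ± 0.033, DNAJA1 at -0.59 ± 0.037 and HSP90AA1 at -0.48 ± 0.034. In the unfolded protein and ATF4 list 17 of 24 fell and 2 rose (17 and 2 adjusted over the list alone; median -0.52), with ATF3 at -2.61 ± 0.049, the serine synthesis gene PSAT1 at -1.70 ± 0.062, MTHFD2 at -1.28 ± 0.051 and PDIA4 at -0.86 ± 0.035. In the cholesterol and fatty acid list 17 of 25 fell and 2 rose (17 and 2 adjusted over the list alone; median -0.38), with HMGCS1 at -0.89 ± 0.042, SQLE at -1.05 ± 0.052 and IDI1 at -0.76 ± 0.045. All 13 mitochondrially encoded mRNAs fell (13 adjusted over the list alone; median -0.38), with MT-ND2 at -0.56 ± 0.033, MT-ND1 at -0.46 ± 0.031, MT-ATP6 at -0.47 ± 0.032 and MT-ND4 at -0.42 ± 0.033. Camera adjusted p was 8.53e-06 for heat shock, 6.82e-05 for the unfolded protein list, 0.000133 for cholesterol and 6.82e-05 for the mitochondrial list, and adjusted p was 0.266 for each with an estimated correlation.

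Of 22 TGF-beta pathway genes, 14 rose and 4 fell at 24 h (15 and 5 adjusted over the list alone; median 0.28), with TGFB3 at 1.78 ± 0.065, ID2 at 1.08 ± 0.037, LTBP3 at 0.75 ± 0.040 and the ligand gene TGFB2 at -2.63 ± 0.079. Of 21 forkhead and partner factors, 13 rose and 6 fell (14 and 6 adjusted over the list alone; median 0.31), with ETS2 at 1.26 ± 0.043, CEBPB at 1.64 ± 0.087 and FOXO1 at 1.33 ± 0.080. Of 13 basal markers, 6 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.22), with LAMB3 at 1.33 ± 0.094 and EGFR at 0.42 ± 0.034. Camera adjusted p was 0.00978, 0.0329 and 0.0496 for the TGF-beta, forkhead and basal lists, and adjusted p was 0.266 for each with an estimated correlation. The forkhead call ended without dTAG_0h replicate 1 (adjusted p = 0.0666), dTAG_0h replicate 2 (0.071) or dTAG_24h replicate 2 (0.0561), and with the replicate number as a block (0.0553). The basal call ended without dTAG_0h replicate 1 (0.108) or dTAG_24h replicate 2 (0.0912), with DESeq2 size factors (0.0512), with a minimum of 1 CPM (0.076) and with the replicate block (0.0977).

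Androgen receptor targets went both ways at 24 h, 9 up and 16 down of 29 (10 and 16 adjusted over the list alone; median -0.17, camera adjusted p = 0.0835). Of these, MAF changed by -2.33 ± 0.050, PLPP1 by -1.90 ± 0.044 and NCAPD3 by -1.002 ± 0.047. Luminal genes had 8 up and 9 down of 22 (8 and 10 adjusted over the list alone; median -0.063, adjusted p = 0.618), with CLDN4 at 0.95 ± 0.041 against the lower SPDEF and FOLH1. Of 17 cohesin genes, 7 fell and 2 rose (8 and 3 adjusted over the list alone, median -0.086, camera adjusted p = 0.0835). Among them were ESCO2 (-2.14 ± 0.088), CDCA5 (-1.49 ± 0.071), ESPL1 (-0.92 ± 0.057) and SMC1A (-0.57 ± 0.040). Of 16 neuroendocrine markers, 6 fell and 2 rose (6 and 2 adjusted over the list alone; median -0.19, adjusted p = 0.0917), with CHGB at -0.80 ± 0.068, SRRM4 at -0.22 ± 0.040, PEG10 at 0.37 ± 0.033 and CELF3 at 0.40 ± 0.051.

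The remaining lists did not pass at 24 h. p53 targets had 3 up and 13 down of 24 (median -0.14, adjusted p = 0.068), hypoxia and glycolysis 5 up and 10 down of 23 (0.0835), histones 3 up and 1 down of 13 (0.116), interferon genes 3 up and 8 down of 20 (0.394) and NF-kB genes 3 up and 5 down of 14 (0.618). Epithelial-mesenchymal genes had 5 up and 7 down of 18 (0.714), fibroblast markers 1 up and 2 down of 10 (0.714) and leukocyte markers a median of -0.028 over 6 genes (0.718). Endothelial markers had fewer than 5 tested members in each comparison and were not tested, and leukocyte markers were tested in the dTAG tables and the interaction only.

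**Figure D2:**
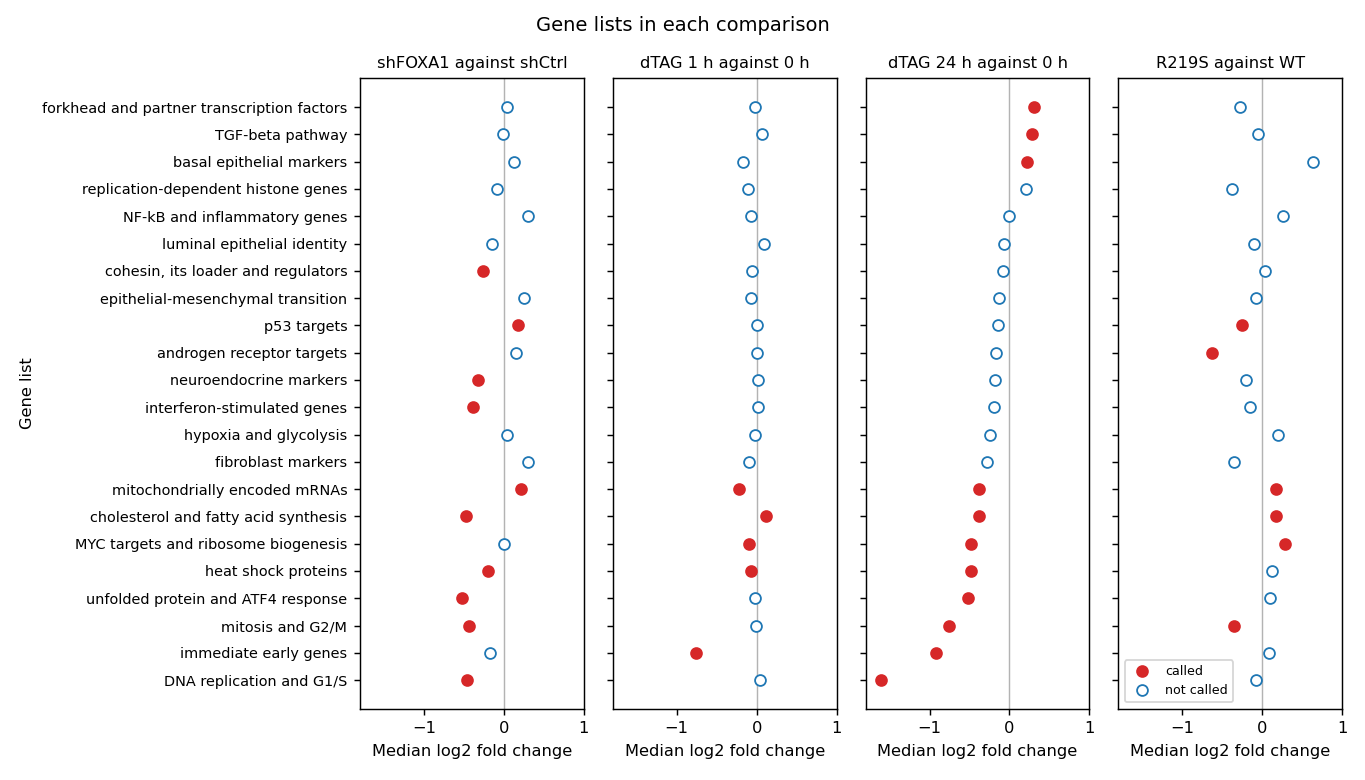
Median log2 fold change of each gene list in the 4 main comparisons (horizontal axis), with filled points for lists called by camera at the preset correlation and open points for the others. DNA replication and G1/S genes had the lowest median at 24 h, -1.61, and immediate early genes the lowest at 1 h, -0.77.

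The R219S comparison asked how cells labelled with the substitution differed from those labelled WT. The prostate kallikrein KLK4 was 439 ± 6.39 CPM in WT and 175 ± 1.63 CPM in R219S (n = 2 each), a log2 fold change of -1.33 ± 0.040. FOLH1, SPDEF and RAB3B changed by -1.76 ± 0.051, -1.61 ± 0.041 and -2.94 ± 0.094. ALDH1A3, which makes retinoic acid, rose from 2.03 ± 0.0603 to 72.5 ± 1.88 CPM, a log2 fold change of 5.15 ± 0.096 (adjusted p = 4.75e-248). The labels do not say whether these libraries received the degrader or came from more than 1 clone, so clone, expression level and substitution were not separated.

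Of 13990 genes tested, 8688 were called, 4272 higher and 4416 lower in R219S, and 1555 changed at least 2-fold (545 higher, 1010 lower). Among the largest rises, the ratio of R219S to WT was 131 (95% interval 23 to 5250) for the kinase gene BMX, 98.3 (33.2 to 480) for CNTNAP5 and 69.2 (23.2 to 339) for PLCXD3, each with 1 to 3 counts in WT. GJA5, a gap junction gene, rose by log2 6.91 ± 0.27, SLAMF1 by 6.05 ± 0.36, S100A14 by 5.94 ± 0.42, the muscle gene MYOT by 5.68 ± 0.21 and the EGF family gene EPGN by 5.65 ± 0.32. The vitamin D binding protein gene GC had 396 counts in WT and 0 in R219S, at least 95.4-fold lower. UGT2B15 was at least 74.7-fold, UGT2B11 at least 45-fold and SLC22A10 at least 35.6-fold lower, each with 0 counts in R219S. ZPLD1 fell from 68.5 ± 1.83 to 0.175 ± 0.0825 CPM. The ratio of WT to R219S was 212 (37.8 to 8420) for PZP, 164 (45 to 1360) for HLA-DQB2, 176 (31.3 to 6990) for DSCAM and 132 (45 to 643) for ST6GALNAC1. HLA-DQB2 and its paralogs can share reads.

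Of 29 androgen receptor targets, 22 fell and 4 rose in R219S (22 and 4 adjusted over the list alone; median log2 -0.64), and camera gave adjusted p = 8.41e-06, and adjusted p = 0.494 with an estimated correlation. Of 26 mitosis and G2/M genes, 23 fell and 0 rose (24 and 0 adjusted over the list alone; median -0.36), with NUSAP1 at -0.53 ± 0.044, BUB1B at -0.56 ± 0.047, TOP2A at -0.45 ± 0.039 and ANLN at -0.47 ± 0.044. By camera the adjusted p was 8.41e-06 for mitosis, and the adjusted p was 0.494 with an estimated correlation. Of 24 p53 targets, 15 fell and 2 rose (15 and 2 adjusted over the list alone; median -0.26), with the death receptor gene TNFRSF10B at -0.83 ± 0.039, TP53INP1 at -0.88 ± 0.046, DDB2 at -0.72 ± 0.057 and PHLDA3 at -0.70 ± 0.060. They had camera adjusted p = 0.00176, and adjusted p = 0.494 with an estimated correlation.

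Of 24 MYC target and ribosome biogenesis genes, 20 rose and 1 fell in R219S (20 and 1 adjusted over the list alone; median 0.28), with UTP20 at 0.85 ± 0.064, RRP9 at 0.71 ± 0.057, NCL at 0.43 ± 0.036 and GNL3, the gene that fell, at -0.55 ± 0.039. The camera adjusted p was 0.000149 for them, and the adjusted p was 0.538 with an estimated correlation. In the cholesterol and fatty acid list 16 of 26 rose and 3 fell (17 and 4 adjusted over the list alone; median 0.17), with SREBF1 at 1.01 ± 0.038 and FADS1 at 0.64 ± 0.041, against FASN, the fatty acid synthase, at -0.59 ± 0.035 and the sterol carrier STARD4 at -1.004 ± 0.052. That list had camera adjusted p = 0.0246, adjusted p = 0.0959 without WT replicate 2, and adjusted p = 0.577 with an estimated correlation. Of 13 mitochondrially encoded mRNAs, 11 rose and 0 fell (11 and 0 adjusted over the list alone; median 0.17), with MT-ND6 at 0.34 ± 0.037, MT-ND1 at 0.30 ± 0.035, MT-ND5 at 0.25 ± 0.034 and MT-CO2 at 0.21 ± 0.034. They had camera adjusted p = 0.0146, and adjusted p = 0.494 with an estimated correlation.

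Luminal genes had 6 up and 10 down of 21 in R219S (6 and 10 adjusted over the list alone; median -0.11, camera adjusted p = 0.364), with CLDN4 at 1.12 ± 0.045. Of 15 neuroendocrine markers, 9 fell and 4 rose (9 and 4 adjusted over the list alone; median -0.21, adjusted p = 0.454), with ENO2 at -1.63 ± 0.068, ONECUT2 at -0.87 ± 0.047, SCG2 at 1.15 ± 0.15 and SRRM4 at 0.35 ± 0.045. Of 17 cohesin genes, 8 rose and 5 fell (8 and 5 adjusted over the list alone; median 0.038, adjusted p = 0.672), with STAG1 at 0.74 ± 0.055, PDS5B at 0.71 ± 0.073, CDCA5 at -0.54 ± 0.050 and ESPL1 at -0.48 ± 0.045. Basal markers had 5 up and 4 down of 13 (median 0.64, adjusted p = 0.507), replication and G1/S genes 3 up and 10 down of 25 (0.257), forkhead and partner factors 8 up and 14 down of 23 (0.257), heat shock proteins 9 up and 5 down of 18 (0.233), hypoxia and glycolysis 14 up and 5 down of 23 (0.205) and immediate early genes 12 up and 8 down of 26 (0.507). Interferon genes had 2 up and 7 down of 20 (0.364), NF-kB genes 7 up and 3 down of 14 (0.233), histones 1 up and 6 down of 12 (0.233), TGF-beta genes 7 up and 10 down of 22 (0.672) and the unfolded protein list 11 up and 9 down of 24 (0.667). Epithelial-mesenchymal genes had 7 up and 6 down of 19 (median -0.075, mean 0.28; 0.968) and fibroblast markers 3 up and 3 down of 9 (median -0.36, mean 0.076; 0.672).

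The joint fit of the depletion times asked which changes differed between 1 h and 24 h, a test in which the 0 h level cancels. Replication and G1/S genes were lower at 24 h than at 1 h by a median log2 of -1.55 (25 of 25 lower), and mitosis genes by -0.69 (26 of 26). Cholesterol and fatty acid genes, of which most rose at 1 h, were lower at 24 h than at 1 h (21 of 25; median -0.44). Immediate early genes did not pass as a list, with 5 higher and 8 lower of 26 (median -0.11, camera adjusted p = 0.886). In all, 9159 of 20027 genes differed, 4247 higher and 4912 lower at 24 h (46.4% higher; 53.5% higher, 4891 against 4259, when scaled by library size only), and 1380 differed at least 2-fold. Camera adjusted p was 5.89e-17 for replication, 1.27e-13 for mitosis and 1.38e-08 for cholesterol, and adjusted p was 0.0724, 0.0724 and 0.119 with an estimated correlation.

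The interaction fit asked whether 24 h of depletion and the hairpin changed the same genes alike. For 4712 of 20795 genes the changes differed, 1966 with a higher and 2746 with a lower change in depletion (41.7% higher; 52.6% higher when scaled by library size only), and 1065 differed at least 2-fold. MAF rose in shFOXA1 and fell at 24 h, with an interaction of -5.07 ± 0.097 (adjusted p = 3.38e-19). TRIB1, a pseudokinase gene, rose by 0.28 ± 0.059 and changed by -2.48 ± 0.053 (interaction -2.74 ± 0.079), and CLU, which encodes the chaperone clusterin, rose by 0.51 ± 0.060 and changed by -1.62 ± 0.033 (interaction -2.12 ± 0.067). Replication and G1/S genes fell in both, but further at 24 h (24 of 25; median difference -1.20), and androgen receptor targets had a lower change at 24 h in 12 of 29 and a higher one in 2 (median -0.43). Camera adjusted p was 4.2e-17 and 0.000321 for these lists, and adjusted p was 0.165 and 0.153 with an estimated correlation. Route, duration and cell derivation differed together between these experiments, and every 24 h change rests on the same 0 h libraries.

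**Figure D3:**
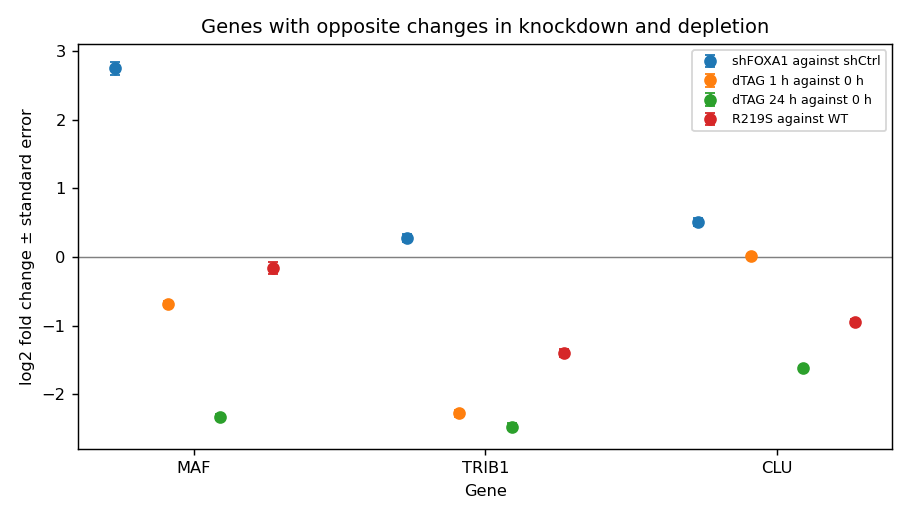
Log2 fold change with its standard error (bars; n = 2 libraries per group) of MAF, TRIB1 and CLU in the 4 main comparisons. All 3 genes were higher in shFOXA1 and lower at 24 h of depletion, and MAF in R219S (-0.16 ± 0.085, adjusted p = 0.0913) and CLU at 1 h (0.019 ± 0.024, adjusted p = 0.647) did not pass the test.

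The called genes of the comparisons were overlapped to ask which changes recurred. Changes in shFOXA1, at 1 h and at 24 h each rose with GC content (Spearman's rho = 0.167, 0.406 and 0.201). Such a shared trend can by itself give calls in the same direction. After the GC correction 20.8% of the shared calls of shFOXA1 and 24 h were opposite, against 19.9% before. The numbers set against independence were not recomputed after the correction. For shFOXA1 and 24 h, 1093 genes were higher in both (475.9 expected from independence) and 1342 lower in both (598.4 expected), while 606 went opposite ways (1068 expected), among 18135 genes tested in both. Across genes, which are not independent replicates, the log2 changes had Pearson's r = 0.30. For 24 h and R219S, 1387 were higher in both (1033 expected), 1712 lower in both (1355 expected) and 1997 opposite (2378 expected; r = 0.310). For shFOXA1 and R219S the numbers were 739 (535.8 expected), 961 (691.6 expected) and 1051 opposite (1222 expected; r = 0.162). For shFOXA1 and 1 h they were 604 (239.8 expected), 409 (218.1 expected) and 428 (460.8 expected, r = 0.0848). With a 2-fold minimum in both, that pair had 14 genes in the same direction and 13 opposite, and DESeq2 calls gave 570 in the same direction. For 1 h and R219S the numbers were 737 (569.4 expected), 540 (484.9 expected) and 1016 (1058 expected, r = 0.0564). For 1 h and 24 h, which share the 0 h libraries, 1130 were higher in both (458.2 expected), 889 lower in both (450.6 expected) and 642 opposite (919 expected). Their r was 0.427, below the 0.512 ± 0.00935 (SD of 20 simulations) that the shared libraries alone gave, while their covariance was 0.0989 against 0.0257 simulated. The simulations gave at most 1 gene called in the same direction in both, but no gene changed in them. With so few calls possible, that number cannot be set against the observed overlap. With 1 library at 0 h given to each comparison, a split chosen after the data were seen, 837 genes were higher and 688 lower in both, with 674 opposite (r = 0.212, covariance 0.0683). The reverse split gave 930, 717 and 515 (r = 0.229, covariance 0.0722), and a deviation common to both 0 h libraries stays in either split.

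Of the 10 largest falls in R219S, 6 were tested at 24 h, and 5 of these fell there too, a comparison chosen after the values were seen. UGT2B11 changed by -4.94, DSCAM by -4.86 and HLA-DQB2 by -4.64 on the log2 scale at 24 h, beside UGT2B15. ZPLD1 was at -1.21 and did not pass (adjusted p = 0.0904). Of the 10 largest rises in R219S, 3 were tested at 24 h, and MYOT rose there by 2.06 (adjusted p = 2.3e-06), while S100A14 (adjusted p = 0.607) and EPGN (adjusted p = 0.566) did not pass.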

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

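The tests of a weaker loss of FOXA1 and of swapped labels were chosen after the opposite changes had been seen, and the test of the GC content correction was set down before any corrected fit was run but after uncorrected GC trends had been seen. The results here were picked out because the effects of 2 groups differed in a test of the difference itself. Between 1 h and 24 h of depletion 9159 genes differed. The lists that differed had these median log2 differences of 24 h from 1 h: DNA replication and G1/S -1.55, mitosis and G2/M -0.69, cholesterol and fatty acid synthesis -0.44, MYC targets -0.33, the unfolded protein and ATF4 response -0.54, heat shock proteins -0.30, basal markers 0.32, mitochondrially encoded mRNAs -0.135, forkhead and partner factors 0.33 and p53 targets -0.14. With an estimated correlation none of these 10 lists passed, with adjusted p from 0.0724 to 0.439.

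Between 24 h depletion and knockdown 4712 genes differed. The 13 lists that differed had these median log2 differences: DNA replication and G1/S -1.20, MYC targets -0.45, immediate early genes -0.86, mitochondrially encoded mRNAs -0.50, mitosis and G2/M -0.34, p53 targets -0.325, androgen receptor targets -0.43, epithelial-mesenchymal transition -0.60, heat shock proteins -0.26, the TGF-beta pathway 0.29, hypoxia and glycolysis -0.37, forkhead and partner factors 0.26, and cholesterol and fatty acid synthesis 0.11. With an estimated correlation none of them passed, with adjusted p from 0.153 to 0.625. The interaction was -5.07 for MAF, -2.74 for TRIB1 and -2.12 for CLU.

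Some genes rose in the knockdown and fell at 24 h of depletion, or the reverse: 606 of the genes called in both comparisons, or 19.9%, below the 1068 expected from independence, and MAF, TRIB1 and CLU were among those with the smallest interaction p. A weaker loss of FOXA1 in the knockdown alone, if the direction of a change does not depend on the degree of loss, leaves opposite calls to false calls. Every false call was taken as called in both with a random direction. This gave 330 opposite calls at the 5% threshold and 488 at the false shares of the simulated data. Both were computed after the value was seen. The 606 lie above both, which argues against a weaker loss as the whole cause only if the simulated false shares hold. The simulations gave both groups of a comparison the same spread. Chi-square per degree of freedom was 11.8 between the shFOXA1 libraries and 4.04 between the shCtrl libraries. A weaker loss as the whole cause is therefore not excluded. Swapped knockdown labels would put FOXA1 higher under shFOXA1, but its highest library was at 304.8 CPM, below the lowest shCtrl library at 402.3 CPM. The trend with GC content had the same sign in shFOXA1 and at 24 h (Spearman's rho = 0.167 and 0.201). Such a trend gives shared rather than opposite directions. Its removal could hardly lower the opposite share, so the 20.8% of shared calls opposite after the correction decide nothing. MAF, TRIB1 and CLU kept their signs after the correction for GC content and transcript length. What also stays open is that the route of FOXA1 loss, its duration and the derivation of the cell lines differed together. A different response to slow partial and fast loss is therefore a candidate explanation that was not tested. A deviation of the 0 h libraries also stays open, since every 24 h change uses them. In CPM of the library total, MAF was 134 and 138 at 0 h, against 9.89 and 10.1 in shCtrl and 17.8 and 18.1 in WT. TRIB1 was 130 and 127 at 0 h, below 222 and 223 in shCtrl, and already 27.4 and 25.6 at 1 h. CLU was 1650 in each 0 h library, above 259 and 272 in shCtrl, and 1690 and 1660 at 1 h.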

How the results depend on the processing

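The GC content and length correction and the split of the 0 h libraries were added after the data were seen, and all other alternatives were planned. Leaving the correction and split aside, no called gene of those named and no called list reversed its direction in any rerun. After the correction MAF, TRIB1 and CLU kept their signs in shFOXA1 and at 24 h. Immediate early genes then had a median of -0.85 at 1 h. The other named genes and lists were not examined under the correction or the split. The majority of calls did turn. With library size only it went from lower to higher at 24 h (5025 higher, 4248 lower) and for 24 h against 1 h (4891, 4259). With that scaling it turned for the interaction too (2539, 2287). It turned in shFOXA1 without shCtrl replicate 2. With a 2-fold minimum it also turned in shFOXA1 (316, 264) and at 1 h (83, 128). Of the comparisons of a named gene with an alternative, 2549 stayed on their side of the threshold and 26 lost the call. For the lists, 662 stayed, 50 lost and 6 gained the call. For the counts, 110 stayed within 1.5-fold and 26 did not. No scaling moved the median of all genes by over 0.1 on the log2 scale.

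With a 2-fold minimum the counts were 580 for shFOXA1, 211 for 1 h, 1544 for 24 h, 1555 for R219S, 1380 for 24 h against 1 h and 1065 for the interaction, as the construction requires. DESeq2 called 2058 genes at 1 h. In the simulated data of that comparison it recovered 56.7% of the 1.5-fold changes, against 79.1% for edgeR. False calls were 0% of its calls and 3.68% of those of edgeR. The lower count goes with this lower recovery of small changes, and the cause was not tested otherwise. Leaving out each library in turn gave 1713 to 6793 genes for shFOXA1 (2421 without shCtrl replicate 1, 1713 without shCtrl replicate 2, 6793 without shFOXA1 replicate 1), and 2232 to 3422 at 1 h (2428 without dTAG_1h replicate 1, 2232 without dTAG_1h replicate 2). It gave 3 to 4 lists at 1 h against 5, the lowest without dTAG_1h replicate 2. In these fits the lone library was assumed to vary like those of the other group. Chi-square per degree of freedom was 11.8 between the shFOXA1 libraries and 4.04 between the shCtrl libraries. Lower counts without a shCtrl library and higher counts without a shFOXA1 library go with this unequal spread. The cause was not tested otherwise. With an estimated correlation 0 lists were called by camera in shFOXA1, at 1 h, at 24 h and in R219S, against 10, 5, 11 and 6 at the preset correlation of 0.01. At an unadjusted camera p under 0.05 the numbers were 0, 2, 3 and 1. Because camera then takes its degrees of freedom from the few libraries, this run cannot tell correlated members from too few libraries. The lists called in shFOXA1, except interferon genes, had estimated correlations above the preset, up to 0.781 for mitosis. Correlated members therefore stay a possible part of the loss. Fry in limma, which tests whether a list moves 1 way on balance and does not compare it with other genes, called 4, 11, 22 and 19 lists. Same-direction overlaps with a 2-fold minimum in both were 14 for shFOXA1 and 1 h (13 opposite), 121 for shFOXA1 and 24 h (34 opposite), 106 for shFOXA1 and R219S (55), 100 for 1 h and 24 h (1), 16 for 1 h and R219S (8), and 290 for 24 h and R219S (66). With DESeq2 calls they were 570 for shFOXA1 and 1 h, 1107 for 1 h and 24 h and 662 for 1 h and R219S. Each of these pairs uses the 1 h calls, and the cause was not tested further.

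With the replicate number as a block, 4412 genes were called for shFOXA1, 3909 at 1 h, 9868 at 24 h, 8441 for R219S, 9296 for 24 h against 1 h and 4539 for the interaction. The deviations of same-numbered libraries correlated across genes at 0.0122, 0.0129, 0.155 and -0.0404 in the 4 main comparisons, and the labels share numbers only, so no block was used. With the block the camera adjusted p was 0.0794 for heat shock proteins at 1 h, and 0.0553 for forkhead factors and 0.0977 for basal markers at 24 h. After the GC correction 4352, 2607, 9307 and 8936 genes were called in the 4 main comparisons. With a minimum of 1 CPM, NF-kB genes (adjusted p = 0.0338) and epithelial-mesenchymal genes (0.0338) passed in shFOXA1.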

Other observations

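The tests of a difference of the 0 h libraries, of an effect of FOXA1 loss by any route and of a GC content trend of the 0 h libraries were chosen after the results had been seen, and the tests of the GC content and length correction were set down before any corrected fit was run but after uncorrected trends had been seen. The genes in the next paragraph were chosen after their values were seen.

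KLK3, KLK2 and TMPRSS2 are androgen-regulated prostate genes, and no test compared R219S with depletion. In R219S KLK3 fell from 21.0 to 3.65 CPM (log2 -2.52 ± 0.12), KLK2 from 75.0 to 22.1 CPM (-1.77 ± 0.062) and TMPRSS2 from 22.0 to 0.739 CPM (-4.89 ± 0.16). At 24 h of depletion KLK3 rose by 0.34 ± 0.039 and TMPRSS2 by 0.65 ± 0.061, while KLK2 changed by -0.36 ± 0.037. In shFOXA1 KLK3 rose by 0.78 ± 0.20 (adjusted p = 0.0292), and TMPRSS2 had 2.21 ± 0.40 without passing (adjusted p = 0.066). The collagen gene COL3A1 was 6.44 CPM in WT and 279 CPM in R219S (5.41 ± 0.062). Close kallikreins can share reads.

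The small nuclear RNA gene RNU6-1 had 58 and 59 counts in the shCtrl libraries, 0 and 0 in shFOXA1, 0 in each library at 0 h and 1 h, and 1 and 2 at 24 h. RAB5IF had 596 and 863 counts in shCtrl and 80 and 92 in shFOXA1, and 154 and 211 counts at 0 h, 414 and 782 at 1 h and 664 and 819 at 24 h. LRRC26 had 104 and 87 counts in shCtrl, 6 and 5 in shFOXA1, 19 and 32 at 0 h, 52 and 134 at 1 h and 79 and 138 at 24 h. FOXA1 was 1021 and 1041 CPM of the library total in WT, 168.8 and 166.4 CPM at 0 h and 406.4 and 437.3 CPM in shCtrl, in separately counted tables.

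Immediate early genes were lower at 1 h and at 24 h than at 0 h. The test of a difference of the 0 h libraries unrelated to depletion, such as handling or medium, gave a median change of -0.114 between 1 h and 24 h, and the 0 h level was above shCtrl by a median log2 of 1.23 (23 of 26 genes) while 1 h was at -0.0825. These medians go with high 0 h libraries as a source, and a fast loss that stays does not by itself predict a 0 h level above shCtrl. FOS, EGR1 and FOSB, picked from the 26 genes, went below the other controls. High 0 h libraries alone predict this only if these genes otherwise lie lower in the dTAG cells than in those controls. That was not tested. In CPM of the library total, FOS was 8.44 at 1 h, against 65.3 in shCtrl and 26.4 in WT. EGR1 was 22 against 120 and 92.1, and FOSB was 3.39 against 11.3 and 11.5. Other members were above shCtrl at every time, such as DUSP2 with 208, 307 and 286 against 12.5. A fast loss is not excluded, because the tables were counted separately and every depletion comparison uses the same 2 libraries at 0 h. In the knockdown the list had a median of -0.174 (adjusted p = 0.222), which does not decide whether FOXA1 loss lowers these genes by any route. The GC content and length correction left a median of -0.85 at 1 h, against -0.765 before, which argues against that trend as the cause.

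Many small changes at 1 h followed the GC content of transcripts. After the correction 2607 genes were called at 1 h against 3850, just past the bound of 2 in 3 of the uncorrected count that had been set for a pattern not caused by the trend. Because the margin was smaller than the standard deviation of the counts with 1 library left out, a condition applied after the value was seen, the trend is left open as the source of part of these calls. The change from 1 h to 24 h had a rho of 0.0202 with GC content, against 0.406 for 1 h against 0 h and 0.201 for 24 h against 0 h, and the knockdown, which has no 0 h libraries, had 0.167. A GC trend of the 0 h libraries is therefore left open as the source, with the condition on the knockdown added after its value was seen, and an early change of many transcripts is not excluded with the same 0 h libraries in both comparisons. With transcript length, rho was -0.272 for 1 h against 0 h and 0.0289 for 24 h against 0 h. It was 0.157 for 24 h against 1 h. A trend of the 0 h libraries alone does not predict these values for length, because it would cancel between 1 h and 24 h.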
